A study of Rattus norvegicus with 35 samples.

How the data were processed

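Livers of male Sprague Dawley rats, 7 weeks old at the start, were profiled on single-colour Affymetrix 3' arrays after 5 daily oral doses of TBB in corn oil at 5 ml/kg, per the labels' protocols. Necropsy followed 1 day after the last dose, and RNA was taken from the left liver lobe, kept in RNAlater, required to have an RNA integrity number of at least 7.0 and amplified with a 3' in vitro transcription kit, per the labels' protocols. The 35 arrays were assigned to vehicle (n = 5) and to 0.05, 0.55, 5.50, 55 and 550 mg/kg (n = 6 each) from their labels, which also gave the replicate numbers.

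The deposited values are log2 expression values per probe set, made by the authors with RMA (by its usual definition background correction, quantile normalisation between arrays and summary over the probes of a set) and the affy package, per the submitters' processing notes. Their versions, the chip definition used and any filter are not given in the sources used here. The values ran on a log2 scale with near-equal quartiles in every array, so no further normalisation was applied. Quantile normalisation gives every array nearly the same distribution, so a change shared by most genes could not be seen, and RMA values level off near background, which shrinks the folds of dim genes. For arrays, the number of arrays limits the precision. The median standard error of a difference from vehicle was 0.085 and the median 95% half-width 0.17 on the log2 scale.

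Of the 31099 probe sets in the table, 57 Affymetrix controls were left out and 31042 tested. A platform annotation gave 20826 of them a single gene symbol and 436 several symbols, and 9780 were not listed with a gene. No gene was named from a probe set with several symbols. Symbols were checked through Entrez identifiers against the reference gene table of the GRCr8 assembly, where 20758 probe sets matched. That table was used for names alone, and no coordinates are given, since no build goes with the expression values.

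The design text describes each dose compared with vehicle with an R package for microarray linear models at a false discovery rate under 5%. That package was not used here; the comparisons were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts, eBayes), with 1 mean per group over all 35 arrays, two-sided, with Benjamini-Hochberg adjustment within each comparison and adjusted p under 0.05 as the threshold. The comparisons were the 5 doses against vehicle, 550 against 55 mg/kg, and a slope on dose rank from 0 to 5. Files were read with the R package data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

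Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, on 1 probe set per gene (the one with the highest mean), for the 5 doses against vehicle and 550 against 55 mg/kg. The 26 lists with at least 5 measured members gave 156 tests, which were adjusted together. The 19 pathway lists were targets of CAR and PXR, AhR, NRF2, PPARalpha and p53, and genes of cholesterol, fatty acid and bile acid synthesis, thyroid hormone handling, glucose metabolism, cell cycle, endoplasmic reticulum stress, heat shock, immediate early response, acute phase, circadian clock, male-biased expression, and pericentral and periportal hepatocytes. The 7 cell type lists were hepatocyte, Kupffer cell, endothelial, stellate cell, cholangiocyte, lymphocyte and neutrophil markers. A list of red blood cell markers had 4 measured members and was not tested. Some genes stand on more than 1 list, among them Nqo1, Cyp1a2, Me1 and Ephx1. A list's score is the mean log2 value of its members in an array, and its difference from vehicle has a 95% interval from the same one-factor model.

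The groups, comparisons, lists, alternatives and the rule for naming genes were fixed before the data were examined. Named genes were, at 550 and 55 mg/kg against vehicle, the 10 largest increases and 10 largest decreases among single-symbol probe sets past the threshold with all treated arrays on the same side of the vehicle mean, using the probe set with the smallest p for each gene. For the other comparisons and the trend the rule took 5 and 5. For each list at 550 mg/kg it took up to 4 called members with the largest change, or otherwise the member with the smallest p. Cyp1a1, Cyp1a2, Cyp2b1, Cyp3a23-3a1, Cyp4a1, Cyp7a1 and Nqo1 were named whatever their values, but Cyp2b1 had no single-symbol probe set and so no value here.

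The alternatives were leaving out the 40% dimmest probe sets, subtracting array medians, cyclic loess between arrays, eBayes with trend and robust settings, a linear model without variance moderation, fitting only the 2 groups compared, array weights, the replicate number as a block, leaving out each array of the groups compared in turn (for the trend, each vehicle and 550 mg/kg array), 1 probe set per gene, a change of at least 1.5-fold, and an estimated correlation or the mean of all probe sets of a gene for the lists. A fit without array 1 of the 5.50 mg/kg group and, for the trend, the omission of each array of the other groups were added after seeing the data. For each count, 100 splits of the same arrays were refitted.

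The procedure was tested on simulated data for 550 mg/kg against vehicle with 31042 probe sets. It recovered 54 of 67 changes of 0.5 (80.6%), 62 of 67 of 1 (92.5%) and 66 of 66 of 2 on the log2 scale. Of 191 calls 9 were of unchanged probe sets, and 2 of 2 shifted lists and 0 others were called. Each simulated probe set varied independently of the others, with the same spread in every group. The list result therefore says nothing about false list calls among correlated genes.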

Results

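Liver expression was measured in male Sprague Dawley rats given TBB, a brominated benzoate ester used as a flame retardant, by gavage in corn oil on 5 consecutive days. There were 5 vehicle arrays and 6 arrays at each of 0.05, 0.55, 5.50, 55 and 550 mg/kg, 35 in all. Each array gave log2 expression values for 31042 probe sets, 20826 of which carried a single gene symbol and stood for 14217 genes. The arrays resembled one another closely, with pairwise correlations across probe sets from 0.988 to 0.996 and no identical pair. The labels name the arrays as separate samples of a group but do not say that each came from its own animal, so p-values measure only the spread between these samples, which may be technical. With these group sizes the median 95% half-width of a difference from vehicle was 0.17 on the log2 scale. The 3' minus 5' differences of the beta-actin, GAPDH and hexokinase control probe sets, a sign of RNA quality, gave 95% intervals that included 0 at every dose against vehicle. Every change below is given on the log2 scale with its standard error, and every adjusted p is from limma unless a gene list is named.

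The highest dose was compared with vehicle to ask which transcripts 5 daily doses of 550 mg/kg changed. Cyp1a1, a cytochrome P450 and classic target of the aryl hydrocarbon receptor (AhR), rose from 4.53 ± 0.20 (SD, n = 5) in vehicle to 11.86 ± 0.37 (SD, n = 6), a change of 7.34 ± 0.24 or 162-fold (adjusted p = 7.7e-22). Its relative Cyp1a2, already among the brightest genes in vehicle, rose 2.05-fold (1.03 ± 0.05, adjusted p = 3.4e-16). The acyl-CoA thioesterase gene Acot1 rose by 3.16 ± 0.43 and Ehhadh, which encodes a peroxisomal oxidation enzyme, by 1.07 ± 0.11. Nqo1, a quinone oxidoreductase gene, rose by 1.76 ± 0.15, and the glutathione S-transferase gene Gsta3 by 1.79 ± 0.24. In the other direction, A2m, which encodes the protease inhibitor alpha-2-macroglobulin, fell by 1.61 ± 0.25 and the apolipoprotein genes Apoa4 and Apoa1 fell by 0.75 ± 0.11 and 0.51 ± 0.06. In all, 155 probe sets passed adjusted p under 0.05, 110 higher and 45 lower. Those with 1 symbol stood for 125 genes, 90 higher and 35 lower. The count fell to 77 without vehicle replicate 3, to 82 without vehicle replicate 1 and to 88 without 550 mg/kg replicate 2. It was 41 when only the arrays of these 2 groups were fitted, and 37 of the 155 probe sets changed by at least 1.5-fold.

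**Figure D1:**
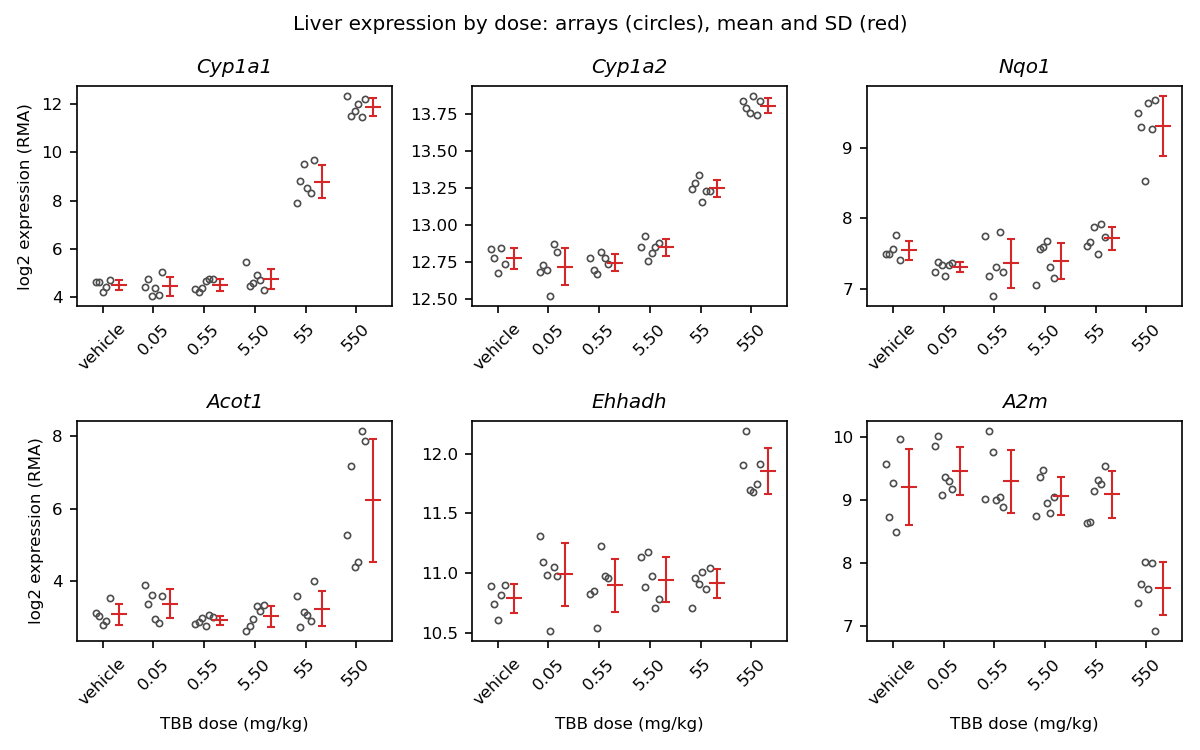
Log2 expression of 6 genes in each array (circles, y axis) by TBB dose in mg/kg (x axis), with the group mean and SD in red; vehicle has 5 arrays, each dose 6, and the y axes differ between panels. Cyp1a1 and Cyp1a2 lie above vehicle at 55 and 550 mg/kg, whereas Nqo1, Acot1 and Ehhadh are higher and A2m is lower at 550 mg/kg.

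Of the AhR targets, 3 of the 7 measured genes rose at 550 mg/kg and none fell: Cyp1a1, Cyp1a2 and Nqo1, the last an NAD(P)H quinone oxidoreductase that is also on the NRF2 list. Adjusted over the list alone, 4 rose and 0 fell. The list was shifted upward (camera, adjusted p = 6.1e-15), with a median change of 0.19 and a mean of 1.44, and the call held with an estimated correlation between genes (adjusted p = 6.0e-06). Much of that mean came from Cyp1a1, which changed by 7.34, so it does not describe a rise across the list. Leaving out the dim probe sets removes dim members of this short list. The median of those left was 1.03, the change of Cyp1a2, so it shows no wider response. Nqo1 passed with adjusted p = 2.8e-09, a 3.39-fold increase. Cyp1a1 in vehicle lay at percentile 41.0 of all probe sets, so its fold depends on the background level of the array. The hepatocyte marker score was -0.11 (95% interval -0.18 to -0.033) from vehicle in the same arrays.

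Of the PPARalpha targets, genes of fatty acid uptake and oxidation under a nuclear receptor for fatty acids, 7 of the 39 measured rose at 550 mg/kg and none fell, and 31 had a positive change. Adjusted over the list alone, 15 rose and 2 fell. Acot1 rose 8.95-fold (adjusted p = 5.5e-05), Ehhadh 2.09-fold (adjusted p = 4.2e-07) and the mitochondrial thioesterase Acot2 2.09-fold (adjusted p = 7.0e-06). Eci1, an enoyl-CoA isomerase of mitochondrial oxidation, rose by 0.96 ± 0.12 (adjusted p = 1.7e-05) on its most significant probe set, while the probe sets of the gene ranged from -0.09 to 0.96. Cyp4a1, a fatty acid omega-hydroxylase, rose by 0.85 ± 0.14 (adjusted p = 8.0e-04). The list was shifted upward (camera, adjusted p = 6.1e-15), with a median of 0.15. This call held with an estimated correlation (adjusted p = 0.020). Acot1 varied widely within the 550 mg/kg group, from 4.38 to 8.15, and lay at percentile 12.6 in vehicle. Its adjusted p ranged from 3.7e-05 to 0.083 over the alternative settings, the highest value coming when only the 2 groups were fitted. In these arrays the hepatocyte marker score was -0.11 (-0.18 to -0.033) from vehicle.

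Of the NRF2 and glutathione genes, which act in the antioxidant response, 4 of 25 measured members rose at 550 mg/kg and none fell, and adjusted over the list alone 8 rose and 0 fell. Gsta3, a glutathione S-transferase, rose 3.46-fold (adjusted p = 2.5e-05) and Nqo1 3.39-fold. Gsr, the glutathione reductase, rose by 0.45 ± 0.09 (adjusted p = 0.014) and Txn1, a thioredoxin, by 0.22 ± 0.05 (adjusted p = 0.038). The list was shifted upward (camera, adjusted p = 1.4e-08), with a median of 0.13, and the call held with an estimated correlation (adjusted p = 0.041). The call of Gsr was lost without vehicle replicate 1 (adjusted p = 0.062), and that of Txn1 without any 1 of the 11 arrays except 550 mg/kg replicate 3 (highest adjusted p = 0.10). Subtracting array medians or fitting only the 2 groups also ended the call of Txn1 (adjusted p from 0.0090 to 0.23 over its alternatives). The difference of the hepatocyte marker score from vehicle was -0.11 (-0.18 to -0.033).

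Of the CAR and PXR targets, genes of drug metabolism and transport under a pair of xenobiotic receptors, 3 of 20 measured members rose and 1 fell at 550 mg/kg, with the same counts adjusted over the list alone. Abcc3, an export pump of the hepatocyte, rose 2.08-fold (1.06 ± 0.20, adjusted p = 0.0047) from percentile 49.8 in vehicle. The retinaldehyde dehydrogenase gene Aldh1a1 rose by 0.64 ± 0.14 (adjusted p = 0.016) and the carboxylesterase gene Ces2c by 0.38 ± 0.09 (adjusted p = 0.026). Slco1a4, an organic anion uptake transporter, fell by 0.30 ± 0.07 (adjusted p = 0.049). Cyp3a23-3a1 differed by 0.23 ± 0.10 without passing (adjusted p = 0.49), and Cyp2b1 had no probe set with a single symbol and so no value here. The list as a whole did not pass (camera, adjusted p = 0.18, median 0.09), although it did without 550 mg/kg replicate 3 (adjusted p = 0.036; with all arrays, adjusted p = 0.71 with an estimated correlation). Fitting only the 2 groups ended the calls of Abcc3, Ces2c and Slco1a4, whose adjusted p ranged over their alternatives from 0.0017 to 0.11, from 0.016 to 0.16 and from 0.021 to 0.15. The call of Aldh1a1 was lost without vehicle replicate 3 (adjusted p = 0.086). That of Ces2c was lost without any 1 of vehicle replicates 1 and 3 and 550 mg/kg replicates 1, 2 and 5 (highest adjusted p = 0.15), and that of Slco1a4 without any 1 array except vehicle replicate 3 (highest adjusted p = 0.16).

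Of the cell cycle genes, 2 of 27 measured members rose at 550 mg/kg and none fell, and 21 had a positive change. Mki67, a marker of proliferating cells, rose by 0.81 ± 0.17 (adjusted p = 0.013) from a dim vehicle level at percentile 29.3, and Ccnb2, a B-type cyclin, by 0.94 ± 0.23 (adjusted p = 0.044). Adjusted over the list alone, 12 rose and 1 fell. The upward shift of the list (camera, adjusted p = 4.7e-07, median 0.15) was not called with an estimated correlation (adjusted p = 0.51). The call of Mki67 was lost without vehicle replicate 1 (adjusted p = 0.078). That of Ccnb2 was lost without any 1 of vehicle replicates 1, 2, 3 and 5 and 550 mg/kg replicates 1, 3, 5 and 6 (highest adjusted p = 0.20). Fitting only the 2 groups ended the call of Mki67 (adjusted p from 0.011 to 0.25 over its alternatives), and 7 of 9 alternatives ended that of Ccnb2 (0.030 to 0.23). Beside these genes, the hepatocyte marker score was -0.11 (-0.18 to -0.033) from vehicle.

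Of the cholesterol synthesis genes, all 20 measured members had a negative change at 550 mg/kg, but none passed on its own or adjusted over the list alone. The isomerase gene Idi1 differed by -0.55 ± 0.18 (adjusted p = 0.23). The list was shifted downward (camera, adjusted p = 6.3e-06, median -0.24), a call that was lost with an estimated correlation (adjusted p = 0.81). The hepatocyte marker score was -0.11 (-0.18 to -0.033) from vehicle in these arrays. Fatty acid synthesis genes did not shift (camera, adjusted p = 0.95, median -0.003, mean 0.03, tested direction up), and Me1, the malic enzyme, differed by 0.56 ± 0.15 (adjusted p = 0.080; 0.045 with array weights). Adjusted over the list alone, 1 of its 19 members rose. Bile acid synthesis and transport genes did not shift either (camera, adjusted p = 0.95, tested direction up, median -0.04, mean -0.003). Their member Akr1d1, a steroid reductase of bile acid synthesis, rose by 0.28 ± 0.07 (adjusted p = 0.047), and adjusted over the list alone 2 of 17 rose. Akr1d1 lost its call without any 1 of vehicle replicates 1, 2, 3 and 4 and 550 mg/kg replicates 2, 4, 5 and 6 (highest adjusted p = 0.19) and with array medians subtracted, cyclic loess or only the 2 groups fitted (0.018 to 0.32 over its alternatives), and its probe sets ranged from 0.06 to 0.28. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.08 ± 0.34 (adjusted p = 0.97).

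Of the thyroid hormone handling and response genes, Dio1, the deiodinase of the liver, fell by 0.49 ± 0.09 (adjusted p = 0.0052), the single call among 12 members, and the list did not pass (camera, adjusted p = 0.53). Adjusted over this list alone, 1 rose and 1 fell. Of 17 acute phase genes A2m alone fell (3.06-fold, adjusted p = 2.0e-04), 2 rose and 4 fell adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.46). No member passed in the lists of glucose metabolism, p53 targets, endoplasmic reticulum stress, heat shock, immediate early, circadian clock and male-biased genes. Their camera adjusted p values were 0.64, 0.11, 0.46, 0.48, 0.95, 0.43 and 0.95. Adjusted over each list alone, 1 heat shock gene fell and the other lists had 0 calls. The members with the smallest p were Fbp1 (-0.14 ± 0.05, adjusted p = 0.32), Aen (-0.26 ± 0.10, 0.35), Ddit3 (-0.32 ± 0.15, 0.52), Hsph1 (-0.44 ± 0.12, 0.085), Ier2 (-0.39 ± 0.23, 0.68), Per2 (0.20 ± 0.07, 0.22) and Hsd3b5 (0.12 ± 0.07, 0.71). Hsph1 passed without vehicle replicate 2 (-0.52, adjusted p = 0.039) and with array weights (0.048). The p53 list passed without vehicle replicate 5 (adjusted p = 0.031) and without 550 mg/kg replicate 6 (adjusted p = 0.041), and with all arrays had adjusted p = 0.71 with an estimated correlation. Fitting only the 2 groups ended the call of Dio1 (adjusted p from 0.0033 to 0.085 over its alternatives).

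Markers of the cell types of a liver lobe were read in the same way at 550 mg/kg. Hepatocyte markers were shifted downward (camera, adjusted p = 0.0069, median -0.068), a call lost with an estimated correlation (adjusted p = 0.25) and with only the 2 groups fitted (adjusted p = 0.083). Their median was -0.033 without 550 mg/kg replicate 5 (adjusted p = 0.024). Of their 11 members Apoa1 alone fell, over all genes (adjusted p = 7.3e-06) and adjusted over the list alone. Pericentral hepatocyte genes were shifted upward (camera, adjusted p = 0.0041, median 0.054; adjusted p = 0.42 with an estimated correlation), and Cyp1a2 was the single call among their 10 members on either adjustment. Cyp1a2 is on the AhR list as well, and this list was not tested without it. The pericentral median was 0.083 without vehicle replicate 1 (adjusted p = 0.0010), 0.024 without vehicle replicate 2 (adjusted p = 0.029) and 0.030 with array weights (adjusted p = 0.014). Periportal genes did not pass (camera, adjusted p = 0.23) but did without 550 mg/kg replicate 3 (adjusted p = 0.017; with all arrays, adjusted p = 0.95 with an estimated correlation). Of these, 1 of 12 was lower adjusted over the list alone, and Asl differed by -0.22 ± 0.07 (adjusted p = 0.22). All 9 Kupffer cell and macrophage markers had a negative change, with a median of -0.22 and Clec4f at -0.34 ± 0.20 (adjusted p = 0.68). The Kupffer list did not pass (camera, adjusted p = 0.11). It passed without 550 mg/kg replicate 1 (adjusted p = 0.014) or 5 (adjusted p = 0.040) and with only the 2 groups fitted (adjusted p = 0.0059), all at the preset correlation. With an estimated correlation its adjusted p was 0.98. Endothelial, stellate, cholangiocyte, lymphocyte and neutrophil markers did not pass, with camera adjusted p values of 0.49, 0.36, 0.95, 0.67 and 0.93 and 0 calls over all genes or adjusted over each list alone. The stellate list passed without vehicle replicate 2 (adjusted p = 0.048; with all arrays, adjusted p = 0.98 with an estimated correlation). The lead members of these lists were Stab1 (-0.24 ± 0.09, adjusted p = 0.35), Pdgfrb (-0.30 ± 0.15, 0.56), Spp1 (0.20 ± 0.14, 0.76), Cd3g (-0.31 ± 0.12, 0.37) and Cxcr2 (-0.10 ± 0.10, 0.86), and the probe sets of Pdgfrb ranged from -0.30 to 0.09.

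Several of the largest changes at 550 mg/kg lay outside these lists, each with all 6 treated arrays on one side of the vehicle mean, as the naming rule required. Adh1c, an alcohol dehydrogenase, rose by 0.98 ± 0.19 (adjusted p = 0.0052) and Acsm5, a medium-chain acyl-CoA synthetase, by 0.98 ± 0.22 (adjusted p = 0.030). The retinol-binding protein gene Rbp7 fell by 0.92 ± 0.16 (adjusted p = 0.0016) and the retinol dehydrogenase gene Rdh5 by 0.69 ± 0.09 (adjusted p = 1.7e-05). The zinc transporter Slc30a3 fell by 0.78 ± 0.16 (adjusted p = 0.0088), the aminoacylase Acy3 by 0.63 ± 0.10 (adjusted p = 4.4e-04) and Apoa4 1.68-fold (adjusted p = 8.3e-05). Pbsn, known as a prostate protein, fell by 1.86 ± 0.42 (adjusted p = 0.028) and the serpin Serpinb9b by 1.56 ± 0.36 (adjusted p = 0.034). The matrix gene Comp fell by 0.72 ± 0.16 (adjusted p = 0.019) and the adhesion molecule Nrcam by 0.62 ± 0.13 (adjusted p = 0.016). Within genes, probe sets ranged from 0.55 to 0.98 for Adh1c, from -0.69 to -0.23 for Rdh5 and from -0.62 to -0.07 for Nrcam. Comp, Rbp7 and Nrcam were dim in vehicle, at percentiles 37.9, 42.3 and 46.8. Calls were lost without single arrays as follows. Slc30a3 was lost without vehicle replicate 1 (adjusted p = 0.055), and Comp without any 1 of vehicle replicates 1, 4 and 5 and 550 mg/kg replicate 3 (highest 0.075). Nrcam was lost without vehicle replicates 3, 4 or 5 or 550 mg/kg replicates 2 or 6 (highest 0.086), and Acsm5 without vehicle replicates 1, 3 or 4 or 550 mg/kg replicates 1, 2, 3 or 5 (highest 0.16). Pbsn was lost without vehicle replicates 1, 2 or 3 or 550 mg/kg replicates 2, 4, 5 or 6 (highest 0.16), and Serpinb9b without any 1 array except vehicle replicate 1 and 550 mg/kg replicate 5 (highest 0.12). Fitting only the 2 groups ended the calls of Acsm5, Adh1c, Nrcam, Slc30a3, Pbsn and Serpinb9b, with highest adjusted p values of 0.071, 0.061, 0.25, 0.071, 0.15 and 0.10 over their alternatives and lowest of 0.018, 0.0023, 0.0095, 0.0063, 0.015 and 0.017. A linear model without variance moderation also ended the calls of Acsm5, Pbsn and Serpinb9b (adjusted p = 0.051, 0.052 and 0.061), and trend and robust eBayes that of Serpinb9b (0.057).

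At 55 mg/kg, the next dose down, limma called 2 probe sets, both higher, and both were AhR targets. Cyp1a1 rose 19.1-fold (4.26 ± 0.24, adjusted p = 2.5e-14), from 4.53 in vehicle to 8.78 ± 0.69 (SD, n = 6), and Cyp1a2 rose 1.39-fold (0.47 ± 0.05, adjusted p = 1.5e-06). Nqo1 (0.17 ± 0.15), Cyp3a23-3a1 (0.13 ± 0.10), Cyp4a1 (-0.02 ± 0.14) and Cyp7a1 (0.34 ± 0.34) did not pass, each with adjusted p = 0.999. The AhR list was shifted upward (camera, adjusted p = 1.4e-09; adjusted p = 1.4e-04 with an estimated correlation), with a median change of 0.12, a mean of 0.69 and 2 of 7 members higher on either adjustment. Much of that mean came from Cyp1a1. Pericentral genes were shifted upward (camera, adjusted p = 6.3e-04; adjusted p = 0.28 with an estimated correlation), with a median of 0.073 and Cyp1a2 the single call among the 10. Cyp1a2 is on the AhR list as well, and the pericentral list was not tested without it. Cholesterol synthesis genes were shifted downward (camera, adjusted p = 1.4e-08, median -0.23), with 0 of 20 members called on either adjustment. Fatty acid synthesis genes (adjusted p = 0.0026, median -0.21) and stellate cell markers (adjusted p = 0.0033, median -0.19) were shifted downward too, again with 0 calls on either adjustment. These 3 downward calls were lost with an estimated correlation, with adjusted p = 0.63, 0.95 and 0.63. PPARalpha targets did not pass at this dose (camera, adjusted p = 0.64, median 0.03). Without 55 mg/kg replicate 1 there were 3 calls, the third being Natd1 (-0.40, adjusted p = 0.038), named after its value was seen, and of the 2 calls Cyp1a1 alone changed by at least 1.5-fold.

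At 0.05, 0.55 and 5.50 mg/kg, limma called 0 probe sets against vehicle, with 1879, 1198 and 1536 at unadjusted p under 0.05 where 1552.1 were expected by chance. The linear model without variance moderation also called 0 at each of these doses. Cyp1a1 differed from vehicle by -0.06 ± 0.24, 0.00 ± 0.24 and 0.22 ± 0.24, and Cyp1a2 by -0.05, -0.03 and 0.07, each ± 0.05. The 95% interval for Cyp1a1 at 5.50 mg/kg ran from -0.26 to 0.70, which bounds the RMA value of a gene dim in vehicle. Cyp7a1 differed by 0.74, 0.47 and 0.75, each ± 0.34 (adjusted p = 0.80, 1.00 and 0.998). Nqo1 differed by -0.24, -0.19 and -0.15, each ± 0.15, Cyp4a1 by 0.02, -0.23 and 0.08, each ± 0.14, and Cyp3a23-3a1 by -0.03, -0.01 and 0.05, each ± 0.10. Without vehicle replicate 4, Defa5, a defensin gene named after its values were seen, was lower at 0.05 (-0.69, adjusted p = 0.0044), 0.55 (-0.65, adjusted p = 0.015) and 5.50 mg/kg (-0.71, adjusted p = 0.0029), and likewise at 550 mg/kg (-0.53, adjusted p = 0.0090) but without a call at 55 mg/kg (-0.53, adjusted p = 0.13). Its group means were 4.48 in vehicle and 3.90, 3.95, 3.89, 4.06 and 4.07 from the lowest dose to the highest, and the vehicle arrays varied most (SD 0.37 against 0.083 to 0.17). These means lay below the array medians of 5.09 to 5.16, so the gene was dim. The differences at the 5 doses share the same vehicle arrays and are not independent. Cyclic loess between arrays also called Defa5 at 5.50 mg/kg (-0.61, adjusted p = 0.048). Without vehicle replicate 5, 1 probe set with no listed gene was higher at 5.50 mg/kg (0.69, adjusted p = 0.046).

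Among the gene lists, none passed at 0.05 mg/kg. At 0.55 mg/kg the Kupffer cell (camera, adjusted p = 0.0066), endothelial (0.0067), endoplasmic reticulum stress (0.030) and PPARalpha (0.036) lists were shifted downward. With an estimated correlation these calls were lost, with adjusted p = 0.95, 0.63, 0.76 and 0.95. At 5.50 mg/kg pericentral genes were shifted upward (adjusted p = 0.0028) and stellate cell markers (0.0033) and NRF2 genes (0.014) downward. These calls were lost as well, with adjusted p = 0.40, 0.63 and 0.68 with an estimated correlation. No single member of these lists passed over all genes. Adjusted over the list alone, 1 AhR gene was lower at 0.05 mg/kg, and 1 PPARalpha and 1 endothelial gene were lower at 0.55 mg/kg.

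**Figure D2:**
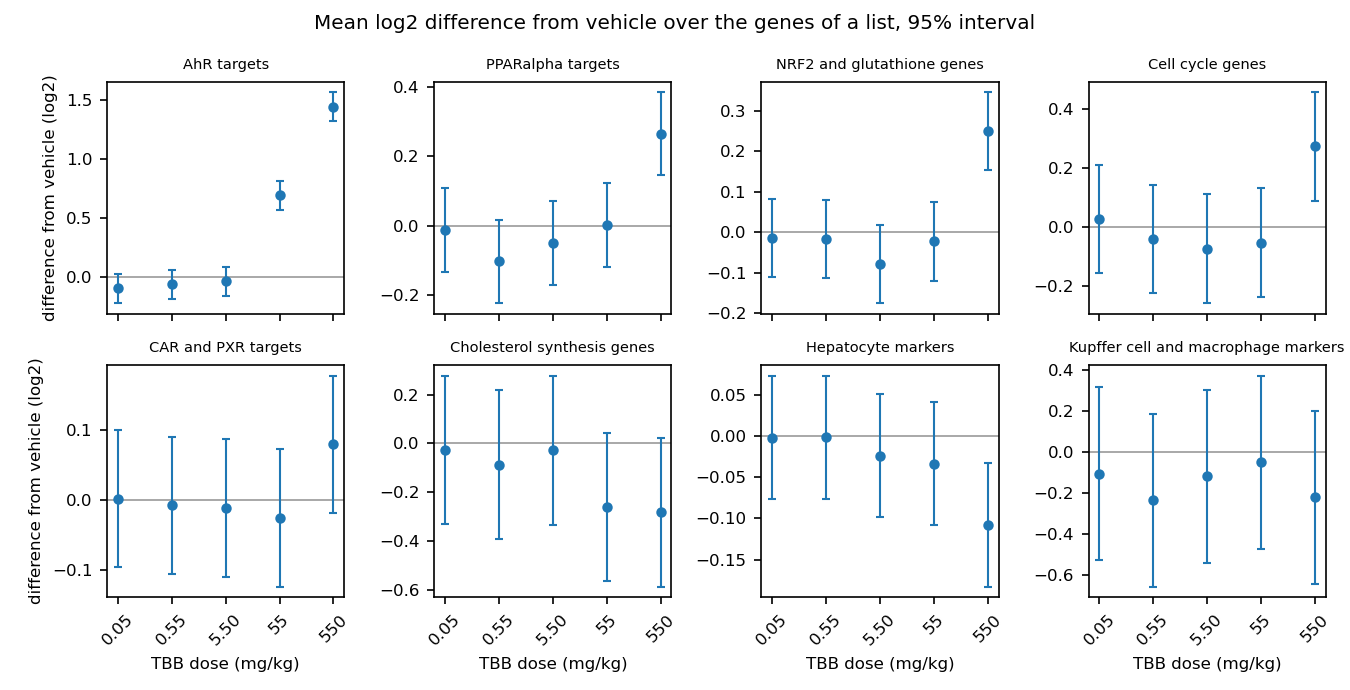
Mean log2 difference from vehicle over the genes of 8 lists (y axis, points) with its 95% interval (bars) by TBB dose in mg/kg (x axis); the y axes differ between panels. The AhR list is above 0 at 55 mg/kg (mean 0.69, median 0.12) and 550 mg/kg (mean 1.44, median 0.19), and the PPARalpha (0.26), NRF2 (0.25) and cell cycle (0.27) lists have intervals above 0 at 550 mg/kg. Much of both AhR means comes from Cyp1a1, which changed by 4.26 and 7.34.

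The highest doses were also set against each other, which tests directly whether the response grew from 55 to 550 mg/kg. Cyp1a1, already called at 55 mg/kg, rose by a further 3.08 ± 0.23 (adjusted p = 9.2e-11). Of genes not called at 55 mg/kg against vehicle, Acot1 was higher by 3.00 ± 0.41 (adjusted p = 6.0e-05) and Nqo1 by 1.59 ± 0.15 (adjusted p = 1.2e-08). Gsta3 was higher by 1.39 ± 0.22 (adjusted p = 5.9e-04) and Cdkn3, a phosphatase of the cell cycle, by 1.34 ± 0.27 (adjusted p = 0.0074). The mean of Cdkn3 was 6.06 in vehicle, 5.77 at 55 mg/kg and 7.11 at 550 mg/kg. Serpinb9b fell by 1.70 ± 0.34 (adjusted p = 0.0083), Apoa4 by 0.77 ± 0.10 (adjusted p = 3.6e-05) and Rdh5 by 0.57 ± 0.08 (adjusted p = 1.8e-04), and A2m fell 2.82-fold (adjusted p = 3.5e-04). Cdkn1a, the cell cycle inhibitor induced by p53, fell by 0.86 ± 0.21 (adjusted p = 0.049). In all, 213 probe sets passed, 179 higher and 34 lower, or 180 genes, 153 higher and 27 lower. The count was 123 without 55 mg/kg replicate 1 and 137 without 55 mg/kg replicate 4, 76 with only these 2 groups fitted, 327 with array weights, and 38 with a change of at least 1.5-fold. Fitting only the 2 groups ended the calls of Acot1, Cdkn3, Serpinb9b and Cdkn1a (adjusted p = 0.055, 0.053, 0.054 and 0.083, the highest over their alternatives, the lowest being 3.4e-05, 0.0039, 0.0033 and 0.023). Cdkn1a was also lost without any 1 of 55 mg/kg replicates 1, 3, 4, 5 and 6 and 550 mg/kg replicates 1, 2, 4 and 6 (highest adjusted p = 0.16), and with array medians subtracted (0.058), trend and robust eBayes (0.068) or no variance moderation (0.073).

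Between these doses 3 lists were higher at 550 mg/kg with both forms of camera. The PPARalpha list rose with 6 of 39 members higher (adjusted p = 1.5e-14; adjusted p = 0.021 with an estimated correlation), the NRF2 list with 6 of 25 (adjusted p = 3.3e-12; 0.010) and the AhR list with 3 of 7 (adjusted p = 1.2e-09; 1.4e-04). Adjusted over each list alone, 19, 13 and 3 rose and 1, 0 and 0 fell. The cell cycle list, with 4 of 27 higher (adjusted p = 1.2e-09), the fatty acid synthesis list, with 1 of 19 (adjusted p = 0.011), and the CAR and PXR list, with 3 of 20 (adjusted p = 0.034), were shifted upward too. Adjusted over each of these lists alone, 12, 1 and 6 rose and 0, 0 and 1 fell. Those 3 calls were lost with an estimated correlation, with adjusted p = 0.30, 0.95 and 0.42. The hepatocyte marker list did not pass between these doses (camera, adjusted p = 0.080), with Apoa1 its single lower member.

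A trend over all 35 arrays, as a slope per step of dose rank from vehicle to 550 mg/kg, passed for 53 probe sets, 30 rising and 23 falling, or 47 genes. The steepest rises per step were those of Cyp1a1 (1.47 ± 0.15, adjusted p = 1.9e-07), Gsta3 (0.31 ± 0.05, adjusted p = 0.0036), Nqo1 (0.30 ± 0.05, adjusted p = 0.0070), Cyp1a2 (0.20 ± 0.02, adjusted p = 2.9e-07) and Adh1c (0.18 ± 0.04, adjusted p = 0.029). The steepest falls were those of A2m (-0.28 ± 0.06, adjusted p = 0.018), Rbp7 (-0.15 ± 0.03, adjusted p = 0.0061), Slc30a3 (-0.12 ± 0.03, adjusted p = 0.027), Nrcam (-0.11 ± 0.02, adjusted p = 0.018) and Rdh5 (-0.10 ± 0.02, adjusted p = 0.020). A slope does not show that a change was graded over the doses. Nqo1 averaged 7.55 in vehicle, 7.31, 7.37, 7.40 and 7.72 from 0.05 to 55 mg/kg, and 9.31 at 550 mg/kg. A2m averaged 9.21 in vehicle, 9.47, 9.30, 9.07 and 9.09 from 0.05 to 55 mg/kg, and 7.59 at 550 mg/kg. Only Cyp1a1 and Cyp1a2 were also called at 55 mg/kg against vehicle. The count fell to 21, 20, 30, 28 and 20 without 550 mg/kg replicates 1, 2, 3, 4 and 6 and rose to 104 without vehicle replicate 2 and to 88 without 55 mg/kg replicate 1 or 6, and 1 probe set had a slope of at least 1.5-fold per step. It was 93 to 141 with 5 other settings. The slopes of Cyp1a1, Cyp1a2, Gsta3, Nqo1 and Rbp7 passed without any 1 of the 35 arrays. A2m lost its call without 550 mg/kg replicates 1, 2, 4 or 6 (highest adjusted p = 0.062), Rdh5 without 550 mg/kg replicates 1, 2, 4, 5 or 6 (0.077) and Nrcam without 550 mg/kg replicates 2 or 6 (0.061). Adh1c lost it without vehicle replicate 3, 0.05 mg/kg replicate 5 or any 1 of the 6 arrays at 550 mg/kg (0.095), and Slc30a3 without vehicle replicates 1, 3 or 5 or 550 mg/kg replicates 1, 2, 3, 4 or 6 (0.087).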

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

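Both tests on 550 mg/kg replicate 3 in this part were chosen only after the result was seen. Within groups of 5 or 6 arrays, 9 of the 182 sets of values examined had a highest or lowest array far from the others by Dixon's test, where 9.1 were expected by chance.

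In the 550 mg/kg group, replicate 3 was far below the other arrays in Nqo1 (8.53 against 9.26 to 9.68), Aldh1a1 (12.01 against 12.32 to 12.47), Gsr (8.78 against 9.02 to 9.17) and Txn1 (12.58 against 12.78 to 12.85), genes of the antioxidant response and drug metabolism. A label swapped with a lower dose is argued against by its Cyp1a1 value, which lay 2.04 above the highest 55 mg/kg array on the log2 scale. A lower dose reaching the sampled animal may account for it and was not settled, since of Cyp1a1, Cyp1a2 and the PPARalpha list score 1 of 3 lay below the other 5 arrays. That score was 0.13 against 0.16 or more, and Gsta3 (8.52 against 8.98 to 9.33), Acot1 (4.38 against 4.53 or more) and the NRF2 list score, which holds Nqo1, Gsr, Txn1 and Gsta3 (0.092 against 0.21 to 0.40), were lowest in this array too, while Cyp1a1, at 11.70, had 2 arrays of its group below it and Cyp1a2, at 13.76, and Ehhadh, at 11.70, had 1 each. A difference between animals in this response stays open as well, untested.

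The other values that stood apart are given without explanation. Gsta3 was 6.56 in vehicle replicate 3 against 7.34 to 7.46 in the other vehicle arrays. Acot2 was 9.31 in vehicle replicate 5 against 8.88 to 8.98. Fbp1 was 12.30 in 550 mg/kg replicate 4 against 12.50 to 12.58. The lymphocyte marker score, relative to the vehicle mean, was 0.18 in 550 mg/kg replicate 1 against -0.18 to -0.07. The median correlation with the arrays of its own group was 0.9912 for 5.50 mg/kg replicate 1 against 0.9940 to 0.9947.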

How the results depend on the processing

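The fit without array 1 of the 5.50 mg/kg group, which moved no count over 1.5 times, and the omission of single arrays at 0.05 to 55 mg/kg for the trend were chosen after seeing the data. The planned fit with surrogate variables is not part of the results given here, because its package could not be used in the final run. Refits were compared for the named genes and, among lists, only for 550 mg/kg against vehicle. None of these results that was past the threshold in either fit changed sign. Of those past it in neither, 8 of 40 gene results and 6 of 19 list results changed sign in at least 1 refit, among them Cyp7a1 at 550 mg/kg (-0.27 to 0.21 with 1 array left out) and the median of immediate early genes (-0.16 to 0.16). For 550 mg/kg against vehicle, the AhR, PPARalpha and NRF2 calls were kept under all 10 alternatives and all 11 single-array omissions. Of results for named genes past the threshold, 429 kept their side and 41 lost it under the other alternatives, and 731 kept and 113 lost it when 1 array was left out. Fits with fewer arrays or groups have fewer residual degrees of freedom, but the cause of the lost calls was not tested for any setting.

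With only the 2 groups fitted, 41 probe sets passed at 550 mg/kg against vehicle and 76 against 55 mg/kg. In that fit the hepatocyte list was not called (median -0.068, adjusted p = 0.083) and the Kupffer list was (median -0.22, adjusted p = 0.0059), though not in the fit of all arrays with an estimated correlation (adjusted p = 0.98). Requiring at least 1.5-fold left 1 probe set at 55 mg/kg, 37 at 550 mg/kg, 38 at 550 against 55 mg/kg and 1 with a trend. Array weights gave 327 at 550 against 55 mg/kg and 141 with a trend. The trend count was 112 without dim probe sets, 93 with cyclic loess, 93 with trend and robust eBayes and 95 with 1 probe set per gene. At 5.50 mg/kg cyclic loess gave 1 call, Defa5 (adjusted p = 0.048). With an estimated correlation, 4 list calls at 550 mg/kg were lost: cholesterol synthesis (median -0.24, adjusted p = 0.81), cell cycle (0.15, 0.51), pericentral (0.054, 0.42) and hepatocyte (-0.068, 0.25).

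Leaving out 1 array of the groups compared at a time, or any 1 of the 35 for the trend, gave 77 to 142 probe sets at 550 mg/kg, 123 to 197 at 550 against 55 mg/kg, 20 to 104 with a trend, 2 to 3 at 55 mg/kg and 0 to 1 at each lower dose. List medians at 550 mg/kg ranged from 0.032 to 0.097 for CAR and PXR targets, -0.28 to -0.14 for Kupffer, -0.13 to -0.044 for periportal, -0.19 to -0.039 for stellate and -0.17 to -0.050 for p53, each with a call in 1 or 2 of the omissions. They ranged from -0.074 to -0.033 for hepatocyte and 0.024 to 0.083 for pericentral genes, called in each.

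No pairing of the arrays by replicate number was detected, though a weak one is not excluded. Of 85 same-numbered pairs, 17 had deviations correlated over 0.1 (median r = -0.009), and 4 of 35 arrays correlated best with their own number. With the replicate block 0, 0, 0, 3, 115, 200 and 43 probe sets passed at 0.05, 0.55, 5.50, 55 and 550 mg/kg against vehicle, at 550 against 55 mg/kg and with a trend. The third call at 55 mg/kg was a probe set with no listed gene, the trend calls of Adh1c and Slc30a3 were lost (adjusted p = 0.069 and 0.0501), as were those of Txn1, Ces2c, Slco1a4, Serpinb9b and Ccnb2 at 550 mg/kg (0.072, 0.056, 0.10, 0.072 and 0.094), and the Kupffer list passed at 550 mg/kg (median -0.26, adjusted p = 0.029, at the preset correlation; adjusted p = 0.98 with an estimated correlation and no block). Dim signal limits the folds of Acot1, Mki67, Comp, Cyp1a1, Rbp7, Nrcam and Abcc3, at percentiles 12.6, 29.3, 37.9, 41.0, 42.3, 46.8 and 49.8 of all probe sets in vehicle.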

Other observations

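The 3 tests on mitochondrial gene sets were chosen only after members of these sets were seen among the calls at 550 mg/kg, and the contrasts of dose shape on the log2 scale and then on linear folds only after the planned comparison of shapes was seen. Of these sets, 1 had a 95% interval above 0 at 550 mg/kg against vehicle and the others had intervals that included 0. The 13 mitochondrial aminoacyl-tRNA synthetase genes, which charge tRNAs for protein synthesis inside mitochondria, had a mean difference of 0.15 (95% interval 0.086 to 0.21), with 10 of 13 positive. This includes Fars2, Iars2 and Tars2, called on a probe set against vehicle or 55 mg/kg, which prompted the test. The other 10, of which 7 were positive, had a mean difference of 0.11 (0.050 to 0.18; camera, adjusted p over the 3 sets = 0.0021; adjusted p = 0.0097 with an estimated correlation). Leaving out called genes follows the change itself, so this is not an independent test. The 78 respiratory chain subunit genes had a mean difference of 0.046 (-0.005 to 0.098), with 64 positive, and camera's call without its called members (adjusted p = 2.9e-06) was lost with an estimated correlation (adjusted p = 0.27). The 73 mitochondrial ribosomal protein genes had a mean difference of 0.028 (-0.039 to 0.095), with 45 positive (camera without its called member, adjusted p = 0.0070; adjusted p = 0.49 with an estimated correlation). The upper ends of both intervals, 0.0976 and 0.0945, lay just under 0.1, a bound chosen only after members of the sets were seen. A larger mean rise in these 2 sets is thus argued against by a narrow margin, and a smaller one is not. As a hypothesis, the highest dose may raise mitochondrial tRNA synthetase transcripts, which rests on genes picked after members were seen and would need this set, now fixed, to be tested in other samples, not analysed here.

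PPARalpha targets were higher at 550 mg/kg, by 0.26 (95% interval 0.14 to 0.38) as a mean over 39 genes. A shift in the time of necropsy is argued against only as far as a clock gene score tracks it. With that score as covariate the PPARalpha difference was 0.27 (0.15 to 0.39). The clock score itself differed by 0.29 with an interval from -0.72 to 1.30, so a shift in time was not excluded. A change in cell composition that enriched hepatocytes would raise the hepatocyte marker score. That score moved the other way, by -0.11 (-0.18 to -0.033), which argues against enrichment only as far as these markers follow hepatocyte content. Apoa1, its single called member, fell by 0.51, and regulation of the markers themselves was not tested. Reduced feed intake may also raise these genes and cannot be told apart from the dose, because the fatty acid synthesis score expected to fall with it differed by 0.033 with an interval from -0.29 to 0.35. Activation of PPARalpha by TBB or a product of it remains a hypothesis beside it, with no feed intake or body weight analysed here.

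Cyp1a1 and Cyp1a2 were called at 55 mg/kg and the PPARalpha list was not, which could be read as different sensitivities. At 55 mg/kg Cyp1a2 had reached 45.8% and Cyp1a1 58.0% of their 550 mg/kg log2 change in RMA value, against 0.698% for the PPARalpha score, and these shares could be changed by compression of Cyp1a1 near background in vehicle (percentile 41.0) or of Cyp1a2 near the top of the scale at 550 mg/kg (13.81, with array maxima of 14.54 to 14.65). In the planned comparison, if the PPARalpha list followed the shape of Cyp1a2, its score at 55 mg/kg would be 0.12 above vehicle; the measured 0.0018 has a 95% interval from -0.12 to 0.12 whose upper end, 0.1219, just reaches the 0.1212 of that shape. In contrasts that carry the errors of both scores and of the share, the score lay below the log2 shape of Cyp1a1 by -0.15 (-0.25 to -0.050) and of Cyp1a2 by -0.12 (-0.22 to -0.016), the upper end for Cyp1a2 reaching 0.0062 without 55 mg/kg replicate 2. On linear folds, where Cyp1a1 had reached 11.3% and Cyp1a2 37.1%, the differences were -0.031 (-0.14 to 0.082) and -0.10 (-0.21 to 0.0016). The log2 shape of Cyp1a1 is thus argued against as far as its RMA values go. On linear folds a shape that the PPARalpha list shares with Cyp1a1, or with Cyp1a2, stays open.

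More probe sets passed at 550 against 55 mg/kg (213) than against vehicle (155). Without any 1 vehicle array the count against vehicle was at most 142. Without 1 of the 55 mg/kg arrays the count against 55 mg/kg was 155 or below in 3 of 6 cases.

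Splits of the same arrays into groups of the same sizes, 100 for each comparison with the real one included, were refitted to count calls. At 550 mg/kg against vehicle 1 split, the real one, gave as many as 155 calls, and the highest other gave 20. At 550 against 55 mg/kg that number was 1, with 213 calls against at most 3, and for the trend 1, with 53 against at most 1. At 55 mg/kg 3 of 100 splits gave 2 or more calls, the highest other giving 4. For these 4 counts the share of splits with as many calls was under 0.05, unadjusted over the comparisons. At 55 mg/kg this rests on 2 calls, and another split gave more. The splits reshuffle only these arrays, whose spread may be technical, so they do not exclude chance between animals. At 0.05, 0.55 and 5.50 mg/kg, with 0 calls, all 100 splits gave as many by construction, the highest others giving 7, 2 and 1, so the splits say nothing about these counts.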
